A study of Homo sapiens with 7 samples.

How the data were processed

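Poly(A) RNA of human induced pluripotent stem cells was measured in 7 libraries, 3 from cells given a scrambled control siRNA and 4 from cells given an siRNA against YTHDF2. Per the labels' protocols, the cells were kept on Matrigel in mTeSR1 medium, and libraries were made from 500 ng of total RNA by template-switching cDNA synthesis (SMARTer) and Tn5 tagmentation, which does not mark the strand of the RNA. The groups and replicate numbers were taken from the sample labels, and no column of the table lacked a sample.

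The authors deposited a table of raw read counts per gene, not normalized, with the gene annotation used, which is GENCODE version 19 of GRCh37 (hg19) per the file headers. Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic 0.32, Bowtie2 2.3.4.3, TopHat2 2.0.12, SAMtools 1.9, HTSeq 0.11.1 and DESeq2 1.22.1 were used with hg19. The settings of these tools, among them the strand option of the counting and the treatment of reads that map to several places, are not given in the sources used here. All gene identifiers of the table matched the deposited annotation, which also gave gene names, types, coordinates and overlaps, and 24711 genes had no counts in any library. Totals lay between 12231034 and 24162363 counts per library. No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom of at least 6.96), so each was counted as its own sample.

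From the counts, genes were kept by edgeR's filterByExpr (16007 genes), libraries were scaled by TMM factors, and the groups were compared with edgeR 4.0.16 (robust quasi-likelihood fit and test, group as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and the F statistic, and the 95% interval of YTHDF2 uses 5 residual degrees of freedom. CPM are counts scaled to library size with the TMM factors, and log2 CPM a prior count of 2. YTHDF2 was also tested by an exact two-sided permutation test over the 35 splits of the libraries into 3 and 4. Gene lists, 37 in number, were tested where at least 5 members were measured, with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. Levels of genes with 20 or fewer counts over the 3 controls are given as CPM only. The report names YTHDF2, METTL3, METTL14, YTHDF1, YTHDF3, POU5F1, SOX2, NANOG and LIN28A, then up to 12 protein-coding genes per direction with the largest fold change among those past the threshold, with a mean of at least 5 CPM and no overlap between the groups, then the 4 members of each list with the smallest p, of which some are not reported here. These rules, the lists, the tests and most alternatives were fixed before the data were examined.

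GC content was taken from GENCODE version 29 transcripts, for 15730 of the 16007 tested genes (98.3%), 15023 of them from the same transcript identifier. To remove its trend, a loess curve (span 0.4) of each library's log2 CPM deviation from the gene mean against GC content was passed to edgeR as an offset, and genes without a GC value were not corrected. Alternatives were other scalings (DESeq2 factors, upper quartile, library size only), other filters (none, or 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with and without library weights, the replicate number as a block, removal of the gene-length trend with and without the block, protein-coding genes only, other thresholds (0.01, 0.10, or 0.05 with a 1.5-fold change) and leaving out each library. The GC removal, alone, with the block or without knockdown replicate 4, was chosen after seeing the data.

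The tests were tested on simulated data for this comparison, with 200 of the genes changed. With the spread of all 7 libraries (15348 genes), 16% of 2-fold and 94% of 4-fold changes were recovered, and 6% of calls were false. With the spread of the 3 controls (15275 genes) 99% and 100% were recovered. Genes varied independently in these data, without the deviations that many genes share in the real libraries, so these rates need not hold there. With a GC trend added to 3 knockdown libraries at the spread of the controls (15381 genes), 42.2% of calls were false before its removal and 3.9% after. The added trend was a straight line in the same GC values that the removal uses, and shallower than the real trends. It therefore does not test how well the removal works on the real libraries. Genes of the Y chromosome and of X inactivation are left out of all values per gene. Figures were drawn with matplotlib.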

Results

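Human induced pluripotent stem cells, reprogrammed from fibroblasts and able to give rise to the tissues of the body, were transfected with a small interfering RNA (siRNA) against YTHDF2 or with a scrambled control siRNA. YTHDF2 is a cytoplasmic protein that binds mRNA carrying N6-methyladenosine (m6A) and recruits the machinery that shortens poly(A) tails. The comparison asks how transcript levels differ once YTHDF2 is depleted. The cells had grown for 5 days before transfection, which was repeated after 24 h, and were collected a further 24 h later, with 4-thiouridine present for the last 4 h. Libraries of polyadenylated RNA came from 3 control and 4 knockdown samples. The control libraries held 24162363, 13653132 and 13689735 gene counts, and knockdown replicates 1 to 4 held 22287525, 23601228, 24140756 and 12231034. Enough counts to be tested were found for 16007 genes. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

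YTHDF2 (ENSG00000198492.10, chromosome 1, 29063133 to 29096287 on the plus strand of hg19) was depleted in every library labelled as a knockdown. Its level was 50.2 ± 2.85 CPM (counts scaled to library size; SD, n = 3) in the controls and 14.6 ± 2.24 CPM (SD, n = 4) after knockdown. Knockdown replicates 1 to 4 had 17.4, 11.9, 14.7 and 14.4 CPM, and the controls 52.1, 51.6 and 46.9 CPM. The log2 fold change of -1.78 ± 0.24 (SE) left 29.1% of the control level, with a 95% interval of 18.8% to 44.9%. The difference reached p = 0.0286 in a two-sided exact permutation test over the 35 splits of the 7 libraries, the smallest p these splits can give. In edgeR's quasi-likelihood test across all genes YTHDF2 had the smallest p, with a Benjamini-Hochberg adjusted p = 0.057. The related readers YTHDF1 and YTHDF3 had log2 fold changes of -0.18 ± 0.26 and -0.15 ± 0.30, and METTL3 and METTL14, the core of the m6A methyltransferase, 0.07 ± 0.34 and 0.19 ± 0.35. None of these 4 passed the test (edgeR adjusted p = 0.641, 0.733, 0.89 and 0.719), and YTHDF1 and YTHDF3 had the opposite sign when scaled by library size only. Over 22 alternatives the sign differed in 1 for YTHDF1, 4 for YTHDF3, 7 for METTL3 and 4 for METTL14, while YTHDF1 passed in 4, lower, and METTL14 in 2, higher. With the GC trend removed YTHDF3 stood at 0.33 and METTL14 at 0.63.

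LIN28A, an RNA-binding protein of pluripotent cells that blocks let-7 maturation, stood at 1328 ± 34.4 CPM (SD, n = 3) in the controls and 642 ± 179 CPM (SD, n = 4) after knockdown, lower in 4 of 4 knockdown libraries than in any control. Its log2 fold change was -1.05 ± 0.29, and it fell when adjusted over the list alone (edgeR adjusted p = 0.0299, against 0.0577 over all genes). The core factors POU5F1, SOX2 and NANOG had log2 fold changes of 0.70 ± 0.33, 0.73 ± 0.35 and 0.44 ± 0.29, which did not pass the test (edgeR adjusted p = 0.155, 0.161 and 0.29). With the trend of each library with GC content removed they stood at -0.08, 0.62 and 0.75. Among 40 measured pluripotency genes, 7 rose and 4 fell, adjusted over the list alone, and 0 passed over all genes in edgeR, against 7 higher and 5 lower by DESeq2. UTF1, ZSCAN10 and SALL2 rose by log2 fold changes of 2.14 ± 0.54, 1.95 ± 0.51 and 1.42 ± 0.39. None of 5 measured naive pluripotency genes passed in edgeR (0 higher and 1 lower at an unadjusted p under 0.05, and 0 higher and 0 lower of 19 by DESeq2). These 19 include any genes to which DESeq2 gave no adjusted p and which it could not call. DPPA3, SUSD2, TFCP2L1 and DPPA2 at -1.19 ± 0.44, 0.93 ± 0.47, 0.40 ± 0.38 and -0.31 ± 0.32 had the smallest p, the last with the opposite sign under scaling by library size only. In knockdown replicates 1 to 4 the median member deviated from the control mean by 0.55, 0.07, -0.14 and -0.08 for pluripotency and -0.10, 0.19, -0.70 and -0.22 for naive pluripotency genes (log2 CPM). Once the GC trend was removed, higher and lower members, adjusted over the list alone, numbered 5 and 4 for pluripotency and 0 and 0 for naive pluripotency. Leaving out knockdown replicate 4 gave, over all genes, higher and lower counts of 14 and 13 for pluripotency and 1 and 1 for naive pluripotency. In that fit 4697 of all 15919 genes were called higher and 3603 lower. Median log2 fold changes as fitted, with GC removal and without knockdown replicate 4 were 0.24, -0.10 and 0.20 for pluripotency and -0.31, -0.25 and -0.30 for naive pluripotency. The median had the other sign in 4 of 22 alternatives for pluripotency and 5 of 22 for naive pluripotency. GC removal moved the log2 fold change of members named as passing by over 1.5 times, to 0.39 for UTF1, 0.48 for ZSCAN10 and 0.91 for SALL2.

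**Figure D1:**
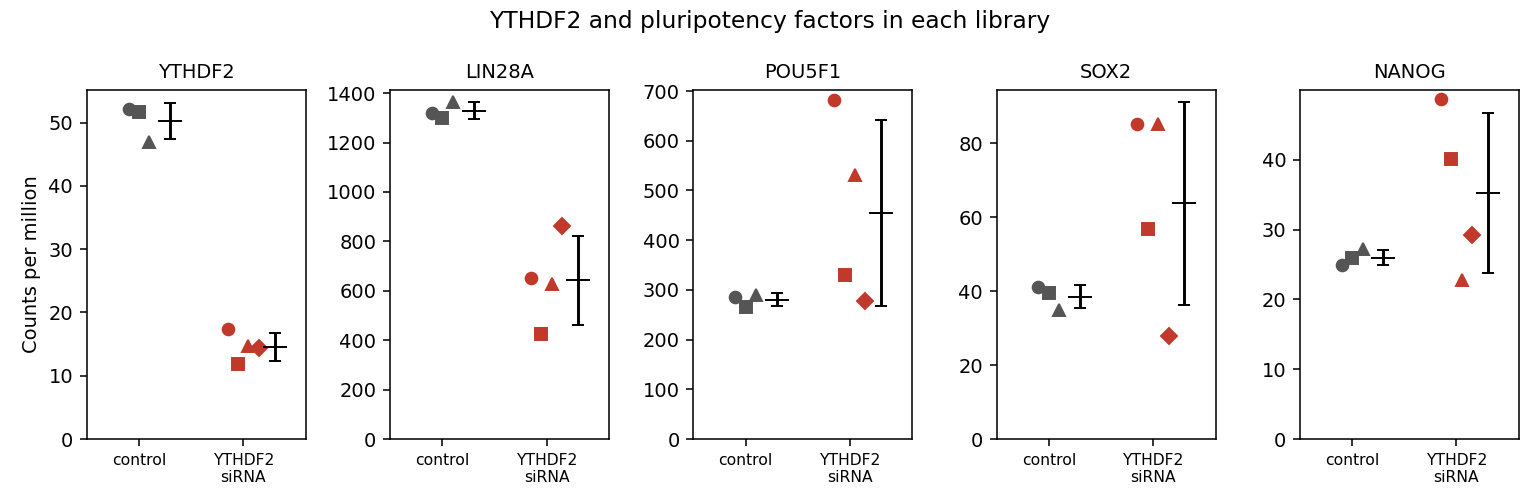
Counts scaled to library size (CPM; y axis, linear, from 0) of YTHDF2, LIN28A, POU5F1, SOX2 and NANOG in 3 control (grey) and 4 YTHDF2 siRNA libraries (red). Symbols are single libraries (circle, square, triangle and diamond for replicates 1 to 4), and black bars give the mean and SD of each group. YTHDF2 and LIN28A are lower in all 4 knockdown libraries, while the other factors overlap between the groups.

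No gene reached an adjusted p under 0.05 in edgeR's quasi-likelihood test of all 7 libraries, and the smallest adjusted p, 0.0572, was shared by 545 genes. At an unadjusted p under 0.05 there were 3633 higher and 1936 lower genes. DESeq2 called 2041 higher and 1065 lower of 33109 genes, of which 18626 had no adjusted p and could not be called. Numbers of list members given for DESeq2 include any such genes. The limma-voom fit called 0, and with library quality weights, lowest for knockdown replicate 4 (0.123), it called 5531 higher and 4452 lower. At an adjusted p under 0.10 edgeR's counts were 2680 higher and 1076 lower. With scaling by library size only, which moved the median log2 fold change of all genes from 0.13 to 0.61, edgeR called 3457 higher and 195 lower genes. Knockdown and control libraries did not overlap for 24.1% of genes, where chance gives 5.7%. The count of 0 depended on 1 library. Without knockdown replicate 4, edgeR called 4697 higher and 3603 lower of 15919 genes, and without each of the other 6 libraries in turn it called 0. Counts of list members without replicate 4 stand against this background, and those at an unadjusted p against 3633 and 1936 of 16007 genes. Such counts, or counts adjusted over a list alone, do not by themselves set a list apart from other genes.

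On the first principal component, which held 64.2% of the variance, the controls stood at -55.1, -60.0 and -61, knockdown replicates 1 to 3 at 93.4, 58.7 and 77.1, and replicate 4, with the controls, at -53.1. Replicates 1 to 3 also differed from the others in the GC content of the transcripts they held. Across protein-coding genes, which are not independent replicates, Spearman's rho of the deviation from the controls with GC was 0.749, 0.571 and 0.716 in knockdown replicates 1 to 3, -0.0228 in replicate 4 and 0.0304, -0.0274 and 0.0261 in each control against the other 2. Mitochondrial ribosomal RNA took 5.5, 5.03 and 6.81% of counts in knockdown replicates 1 to 3, 2.29% in replicate 4 and 2.33, 2.98 and 2.18% in the controls. Genes higher at adjusted p under 0.10 had a median GC content of 59.6%, lower genes 42.3%, and all tested genes 49.0%. With the GC trend of every library removed, a setting chosen after the data were seen, edgeR called 327 higher and 241 lower genes at adjusted p under 0.05.

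**Figure D2:**
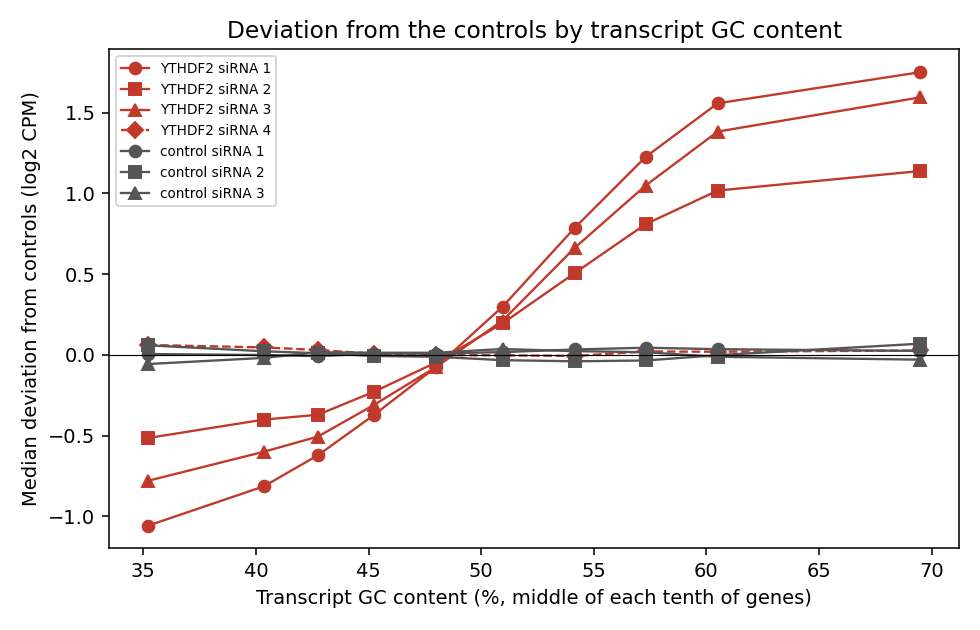
Median deviation of protein-coding genes from the controls (y axis, log2 CPM; each control against the other 2) in 10 bins of transcript GC content (x axis, %), 1 line per library (controls grey, YTHDF2 siRNA red, replicate 4 dashed). Knockdown replicates 1 to 3 run from -1.06, -0.52 and -0.78 in the lowest bin to 1.75, 1.14 and 1.59 in the highest, and replicate 4 and the controls stay within 0.069 of 0.

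Genes of mitosis, oxidative phosphorylation and the cytosolic ribosome lay lower after knockdown as groups, in each of the 4 knockdown libraries under TMM scaling, by camera at its preset correlation. These calls were lost with an estimated correlation (adjusted p = 0.82 for each), and fry called none of these lists (lowest adjusted p = 0.139 over all lists). Across protein-coding genes log2 fold changes fell with mean expression (Spearman's rho -0.42, and -0.36 with the GC trend removed). In the highest of 10 expression bins the median gene stood at -0.589, and at -0.445 with that trend removed. Whether these lists lay lower than other genes of like expression was not tested. Scaled by library size only, the median members deviated in knockdown replicates 1 to 4 by -0.71, 0.33, -0.36 and -0.14 for mitosis, -0.08, -0.31, -0.20 and -0.22 for oxidative phosphorylation, -0.05, -0.25, -0.10 and -0.13 for ribosomal proteins and -0.05, -0.15, -0.15 and 0.10 for mitochondrial genes. The median log2 fold changes were then -0.16, -0.18, -0.13 and -0.06. TMM factors were 1.16, 1.47, 1.16 and 0.859 in the knockdown libraries and 0.841, 0.838 and 0.835 in the controls. Ribosomal protein genes took 12.2, 10.4, 11.9 and 9.98% of all counts after knockdown and 11.2, 10.5 and 10.9% in the controls. In edgeR's test of the 7 libraries no member of any list passed over all genes, whereas DESeq2 called 1 higher and 12 lower for mitosis and 3 higher and 24 lower for oxidative phosphorylation. Among 44 mitosis genes, 7 fell and 0 rose, adjusted over the list alone, around a median log2 fold change of -0.60 (camera on the edgeR fit, adjusted p = 5.1e-05, and adjusted p = 0.82 with an estimated correlation). NUSAP1, a microtubule-associated protein of the spindle, PTTG1 (securin), CCNB2 (cyclin B2) and NDC80, a kinetochore component, fell, at log2 fold changes of -1.30 ± 0.34, -1.07 ± 0.30, -1.01 ± 0.29 and -1.18 ± 0.34. Of 58 nuclear-encoded oxidative phosphorylation genes 16 fell and 3 rose, adjusted over the list alone, around a median of -0.60 (camera on the edgeR fit, adjusted p = 5.1e-05, and adjusted p = 0.82 with an estimated correlation). UQCRFS1 and NDUFA13 rose, at 1.29 ± 0.32 and 1.65 ± 0.41, and NDUFA9 and ATP5G1 fell, at -1.22 ± 0.31 and -1.09 ± 0.30. No single gene passed in edgeR among 83 cytosolic ribosomal proteins (5 higher and 29 lower at an unadjusted p under 0.05, and 1 higher and 10 lower of 85 by DESeq2). Their median was -0.55 (camera on the edgeR fit, adjusted p = 5.1e-05, and adjusted p = 0.82 with an estimated correlation), and RPLP1, RPS26, RPL14 and RPL10 at 1.09 ± 0.38, -0.94 ± 0.34, -0.84 ± 0.30 and -0.92 ± 0.34 had the smallest p. None of 15 mitochondrially encoded genes passed in edgeR (0 higher and 0 lower at an unadjusted p under 0.05, and 0 higher and 0 lower of 15 by DESeq2). They lay at a median of -0.47 (camera on the edgeR fit, adjusted p = 0.038, and adjusted p = 0.82 with an estimated correlation), with MT-CO1, MT-CO3, MT-ND5 and MT-CO2 at -0.78 ± 0.38, -0.74 ± 0.36, -0.67 ± 0.33 and -0.76 ± 0.38. The list also holds the 2 mitochondrial ribosomal RNAs, which went the other way in knockdown replicates 1 to 3. There they took 5.5, 5.03 and 6.81% of counts, against 2.29% in replicate 4 and 2.33, 2.98 and 2.18% in the controls. In knockdown replicates 1 to 4 the median member deviated by -1.18, -0.48, -0.82 and -0.17 for mitosis and -0.55, -1.13, -0.66 and -0.26 for oxidative phosphorylation. For the others it deviated by -0.52, -1.06, -0.56 and -0.16 for ribosomal proteins and -0.52, -0.97, -0.61 and 0.06 for mitochondrial genes. With the GC trend removed the call of the mitochondrial genes was lost, as it was without control replicate 1 or knockdown replicate 2 (camera on the edgeR fit, adjusted p = 0.53, 0.062 and 0.23). With GC removal the counts of higher and lower members, adjusted over the list alone, were 0 and 11 for mitosis and 1 and 29 for oxidative phosphorylation. Further counts were 0 and 0 for ribosomal proteins and 0 and 0 for mitochondrial genes. Without knockdown replicate 4 the counts higher and lower over all genes were 6 and 25 for mitosis and 10 and 32 for oxidative phosphorylation. The rest gave 15 and 56 for ribosomal proteins and 1 and 10 for mitochondrial genes. As fitted, with GC removal and without knockdown replicate 4, median log2 fold changes were -0.60, -0.36 and -0.87 for mitosis and -0.60, -0.58 and -0.73 for oxidative phosphorylation. The same 3 medians were -0.55, -0.48 and -0.71 for ribosomal proteins and -0.47, -0.13 and -0.66 for mitochondrial genes. No alternative turned the sign of these medians. Named members that had passed moved by over 1.5 times with GC removal, to 0.55 for NDUFA13. All 6 calls that camera made among 36 tested lists, the 4 here and WNT and NOTCH signalling, were lost with an estimated correlation, and fry, which tests whether the genes of a list move one way on balance, had a smallest adjusted p = 0.139.

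Histone genes and chromatin regulators changed in both directions, adjusted over the list alone in edgeR's test of the 7 libraries. None of 42 DNA replication genes passed in edgeR (10 higher and 10 lower at an unadjusted p under 0.05, and 4 higher and 8 lower of 42 by DESeq2). FEN1, CHAF1A, CCNE2 and POLD1 at 0.94 ± 0.25, 1.05 ± 0.34, -1.54 ± 0.50 and 1.29 ± 0.42 had the smallest p. Of 42 replication-dependent histone genes 5 rose and 1 fell, adjusted over the list alone. The libraries held polyadenylated RNA, and how far the RNA selection sets the counts of these genes was not tested. HIST1H1D, a linker histone, fell at -1.45 ± 0.33, while HIST1H1E and HIST1H4I rose at 2.76 ± 0.68 and 3.43 ± 0.84, and HIST1H3I had 0 counts in the controls and 0.897 CPM after knockdown. Of 55 chromatin regulators 12 rose and 3 fell, adjusted over the list alone, among them the polycomb subunit CBX2, the histone demethylase KDM6B and the histone deacetylase HDAC4, which rose at 1.63 ± 0.40, 2.43 ± 0.64 and 1.55 ± 0.43. None of 16 host genes of small nucleolar RNAs passed in edgeR (0 higher and 4 lower at an unadjusted p under 0.05, and 0 higher and 3 lower of 16 by DESeq2). The smallest p were those of SNHG5, SNHG8, SNHG14 and SNHG3 at -0.84 ± 0.29, -0.74 ± 0.26, -1.02 ± 0.36 and -0.61 ± 0.28. None of 424 zinc finger genes passed in edgeR (64 higher and 23 lower at an unadjusted p under 0.05, and 26 higher and 10 lower of 482 by DESeq2). ZNF672, ZNF574, ZNF532 and ZNF738 at 1.57 ± 0.38, 1.74 ± 0.43, -0.98 ± 0.25 and -1.38 ± 0.36 had the smallest p. The median member deviated, in knockdown replicates 1 to 4, by -0.47, -0.10, -0.37 and -0.08 for DNA replication and 1.01, 0.23, 1.17 and -0.48 for histones. It deviated by 0.01, -0.01, 0.12 and 0.00 for chromatin regulators, -0.33, -0.29, -0.79 and -0.21 for small nucleolar RNA host genes and -0.10, 0.43, -0.14 and 0.18 for zinc finger genes. The median log2 fold changes of -0.30 for DNA replication and -0.39 for the host genes turned positive under scaling by library size only, and that of 0.03 for chromatin regulators turned negative with DESeq2 or upper-quartile factors. Adjusted over the list alone, members higher and lower after GC removal were 0 and 0 for DNA replication, 5 and 3 for histones and 0 and 0 for chromatin regulators. The rest gave 1 and 3 for host genes and 1 and 1 for zinc finger genes. Only 28 of the 42 histone genes had a GC value, and the others were not corrected. The histone values after GC removal therefore mix corrected and uncorrected genes. Over all genes, leaving out knockdown replicate 4 gave higher and lower counts of 14 and 18 for DNA replication, 11 and 2 for histones and 18 and 10 for chromatin regulators. They were 2 and 6 for host genes and 85 and 64 for zinc finger genes. The median log2 fold changes as fitted, with GC removal and without knockdown replicate 4 were -0.30, -0.20 and -0.31 for DNA replication, 0.57, 0.57 and 0.79 for histones and 0.03, 0.13 and 0.05 for chromatin regulators. The next medians were -0.39, -0.39 and -0.44 for host genes and 0.13, 0.26 and 0.07 for zinc finger genes. The other sign of the median came in 1 of 22 alternatives for DNA replication, 6 of 22 for chromatin regulators, 1 of 21 for host genes and 3 of 22 for zinc finger genes, and never for the others. By over 1.5 times, GC removal moved log2 fold changes of named members that had passed, to 1.70 for HIST1H1E, 0.66 for CBX2, 1.25 for KDM6B and 1.02 for HDAC4. Camera called none of these 5 lists on the edgeR fit of the 7 libraries, and it called them in 3 of 22 alternatives for DNA replication, 6 of 22 for histones, 6 of 21 for host genes and 3 of 22 for zinc finger genes and none for the others.

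Genes that write, read or act on m6A and genes of mRNA decay were followed because YTHDF2 links them. Among 15 m6A writers and erasers 2 rose and 1 fell, adjusted over the list alone. RBM15B and PCIF1 rose at 0.93 ± 0.29 and 1.11 ± 0.36, CBLL1 fell at -0.99 ± 0.32, and the demethylase ALKBH5 stood at 0.59 ± 0.26. Of 13 other m6A readers 1 rose, adjusted over the list alone, PRRC2A at 1.76 ± 0.42, beside ELAVL1, HNRNPC and FMR1 at 0.84 ± 0.29, -0.91 ± 0.33 and -0.65 ± 0.33. None of 47 genes of mRNA decay passed in edgeR (7 higher and 9 lower at an unadjusted p under 0.05, and 5 higher and 6 lower of 47 by DESeq2). The smallest p were those of BTG1, CNOT3, UPF1 and ZFP36L1 at 1.29 ± 0.32, 1.75 ± 0.47, 1.81 ± 0.50 and 1.10 ± 0.34. Of 11 transcripts described as YTHDF2 targets in other cells 2 rose, adjusted over the list alone, EGFR and AXIN1 at 1.80 ± 0.43 and 1.48 ± 0.46, while CREBBP and SOCS2 stood at 0.90 ± 0.37 and 0.72 ± 0.36. Median deviations in knockdown replicates 1 to 4 were -0.46, 0.16, -0.12 and 0.16 for writers and erasers and -0.56, -0.25, -0.36 and 0.12 for readers. The remaining medians were -0.39, -0.31, -0.35 and 0.00 for mRNA decay and 0.94, 0.67, 0.08 and 0.17 for the described targets. Once the GC trend was removed, higher and lower members, adjusted over the list alone, numbered 3 and 0 for writers and erasers and 2 and 0 for readers. They were 6 and 2 for mRNA decay and 3 and 0 for the described targets. Leaving out knockdown replicate 4 gave, over all genes, higher and lower counts of 4 and 5 for writers and erasers and 4 and 6 for readers. Further counts were 11 and 21 for mRNA decay and 4 and 1 for the described targets. Median log2 fold changes as fitted, with GC removal and without knockdown replicate 4 were 0.07, 0.14 and -0.11 for writers and erasers and -0.18, 0.10 and -0.37 for readers. In that order they were -0.26, -0.04 and -0.32 for mRNA decay and 0.72, 0.39 and 0.86 for the described targets. The median had the other sign in 7 of 22 alternatives for writers and erasers, 4 of 22 for readers and 1 of 22 for mRNA decay, and never for the others. GC removal moved the log2 fold change of members named as passing by over 1.5 times, to 0.14 for PCIF1, -0.55 for CBLL1, 0.63 for PRRC2A and 0.34 for AXIN1. Camera called none of these 4 lists on the edgeR fit, and gave calls in 1 of 22 alternatives for mRNA decay and none for the others. The negative medians of the readers (-0.18) and of mRNA decay (-0.26) turned positive under scaling by library size only.

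WNT and NOTCH genes lay higher as groups after knockdown, by camera on the 7 libraries at its preset correlation, and both calls were lost with an estimated correlation. Of 32 WNT pathway genes 9 rose, adjusted over the list alone, around a median of 0.72 (camera on the edgeR fit, adjusted p = 0.049, and adjusted p = 0.82 with an estimated correlation). The receptor FZD2, the ubiquitin ligase ZNRF3, the secreted protein SFRP2 and the scaffold AXIN1 rose at log2 fold changes of 2.46 ± 0.52, 1.28 ± 0.37, 1.13 ± 0.34 and 1.48 ± 0.46. Of 25 NOTCH pathway genes 6 rose, adjusted over the list alone, around a median of 1.06 (camera on the edgeR fit, adjusted p = 0.027, and adjusted p = 0.82 with an estimated correlation). The glycosyltransferases MFNG and LFNG, with NUMBL and HEYL, rose at 1.88 ± 0.45, 1.84 ± 0.47, 1.65 ± 0.42 and 1.44 ± 0.42. Of 39 NODAL, TGF-beta and BMP genes 7 rose, adjusted over the list alone, among them SKI, BMP7, TGFB1 and INHBE at 1.45 ± 0.40, 1.39 ± 0.39, 2.21 ± 0.65 and 1.41 ± 0.42. In knockdown replicates 1 to 4 the median member deviated by 0.73, 0.95, 0.72 and 0.11 for WNT, 1.2, 1.2, 1.26 and -0.08 for NOTCH and 0.91, 0.66, 0.18 and 0.21 for NODAL, TGF-beta and BMP genes. Members had a median GC content of 51.5%, 59.8% and 51.6%. With the GC trend removed camera's calls were lost (adjusted p = 0.053 for WNT and 0.63 for NOTCH on the edgeR fit), and 1 of 22 alternatives for NODAL, TGF-beta and BMP genes gave a call. With GC removal the counts of higher and lower members, adjusted over the list alone, were 3 and 0 for WNT, 0 and 0 for NOTCH and 0 and 0 for NODAL, TGF-beta and BMP genes. Without knockdown replicate 4 the counts higher and lower over all genes were 19 and 2 for WNT, 15 and 3 for NOTCH and 14 and 7 for NODAL, TGF-beta and BMP genes. As fitted, with GC removal and without knockdown replicate 4, median log2 fold changes were 0.72, 0.39 and 0.89 for WNT, 1.06, 0.13 and 1.32 for NOTCH and 0.64, 0.39 and 0.78 for NODAL, TGF-beta and BMP genes. No alternative turned the sign of these medians. Named members that had passed moved by over 1.5 times with GC removal, to 1.12 for FZD2, 0.34 for AXIN1, 0.94 for MFNG, 0.72 for NUMBL, 0.76 for LFNG, 0.64 for HEYL, 0.48 for SKI, 0.73 for BMP7 and 1.02 for TGFB1. The NOTCH call was also lost without knockdown replicate 2 (0.076), and the WNT call without control replicate 1 or 3 or knockdown replicate 1 or 2 (0.084, 0.050, 0.053 and 0.23).

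Neural genes were followed because the series concerns neural differentiation. Of 42 neuronal genes 5 rose and 0 fell, adjusted over the list alone, among them the synaptic adhesion protein NLGN3, L1CAM and NRXN2 at log2 fold changes of 1.93 ± 0.43, 1.5 ± 0.40 and 1.94 ± 0.53, and STMN4 at 0.0292 CPM in the controls, from 1 count in all, and 0.663 CPM after knockdown. Of 46 axon guidance genes 11 rose and 1 fell, adjusted over the list alone, and the neurotrophin receptor NGFR with EPHA2, EPHB2 and PLXND1 rose at 2.58 ± 0.51, 2.42 ± 0.57, 1.19 ± 0.30 and 1.98 ± 0.51. None of 32 neural progenitor genes passed in edgeR (9 higher and 3 lower at an unadjusted p under 0.05, and 5 higher and 1 lower of 52 by DESeq2), with NES and PROM1 at 1.61 ± 0.42 and -1.13 ± 0.34, LHX2 at 0.327 CPM in the controls and 1.98 CPM after knockdown, and DACH1 at 0.206 CPM in the controls and 1.2 CPM after knockdown. Of 11 neural crest genes 2 rose and 1 fell, adjusted over the list alone. NGFR is also in this list, ETS1 fell at -1.18 ± 0.33, SNAI1 rose from 0.533 to 1.55 CPM, and SOX9 stood at 1.41 ± 0.62. Of 15 glial genes 1 rose, adjusted over the list alone, CSPG4 at 1.9 ± 0.42, beside GFAP and CNP at 1.39 ± 0.51 and 0.69 ± 0.26, and MOG at 0.0584 CPM in the controls and 0.441 CPM after knockdown. Of 26 protocadherins 5 rose and 1 fell, adjusted over the list alone: PCDH1 and PCDH19 rose at 1.51 ± 0.42 and 1.35 ± 0.41, PCDHGC3 from 0.469 to 1.64 CPM, and PCDHB16 fell at -1.23 ± 0.33. The median member deviated, in knockdown replicates 1 to 4, by 0.17, 0.39, 0.69 and -0.11 for neuronal, 0.65, 0.51, 0.86 and -0.11 for axon guidance and 0.04, 0.97, 0.91 and 0.04 for neural progenitor. It deviated by -0.61, 0.77, 0.97 and 0.04 for neural crest, 0.22, 0.70, 0.46 and 0.29 for glial genes and 0.78, 0.75, 0.89 and 0.03 for protocadherins. Median GC content lay between 48.4% for protocadherins and 53.8% for neural progenitor genes, against 49.0% over all tested genes. Adjusted over the list alone, members higher and lower after GC removal were 2 and 0 for neuronal, 4 and 2 for axon guidance and 0 and 1 for neural progenitor. The rest gave 1 and 1 for neural crest, 0 and 0 for glial genes and 3 and 1 for protocadherins. Over all genes, leaving out knockdown replicate 4 gave higher and lower counts of 18 and 6 for neuronal, 22 and 5 for axon guidance and 13 and 4 for neural progenitor. They were 3 and 1 for neural crest, 4 and 4 for glial genes and 8 and 1 for protocadherins. The median log2 fold changes as fitted, with GC removal and without knockdown replicate 4 were 0.39, 0.14 and 0.52 for neuronal, 0.60, 0.23 and 0.68 for axon guidance and 0.49, 0.21 and 0.64 for neural progenitor. The next medians were 0.56, 0.22 and 0.90 for neural crest, 0.40, 0.43 and 0.39 for glial genes and 0.51, 0.62 and 0.56 for protocadherins. No alternative turned the sign of these medians. By over 1.5 times, GC removal moved log2 fold changes of named members that had passed, to 1.11 for NLGN3, 0.56 for L1CAM, 0.65 for NRXN2, 1.44 for NGFR, 1.38 for EPHA2, 0.63 for EPHB2, 0.76 for PLXND1, 0.79 for CSPG4 and 0.48 for PCDH1. SNAI1 and PCDHGC3, with few control counts, moved as far. On the edgeR fit of the 7 libraries camera called none of these 6 lists, and it called them in 1 of 22 alternatives for neuronal, 5 of 22 for axon guidance, 2 of 22 for neural progenitor and 2 of 22 for protocadherins and none for the others.

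Markers of other lineages were measured in small numbers. Of 11 trophoblast and amnion genes 3 rose, adjusted over the list alone, the keratins KRT7, KRT18 and KRT8 at 1.27 ± 0.38, 1.27 ± 0.39 and 1.01 ± 0.33, and KRT19 stood at 0.63 ± 0.30. Of 10 mesoderm genes 1 fell, adjusted over the list alone, HAPLN1 at -1.70 ± 0.45, beside PDGFRA at -0.87 ± 0.37, TBX6 at 0.153 CPM in the controls and 0.718 CPM after knockdown, and MESP2 at 0.0875 CPM in the controls and 0.544 CPM after knockdown. None of 11 endoderm genes passed in edgeR (1 higher and 0 lower at an unadjusted p under 0.05, and 1 higher and 0 lower of 27 by DESeq2). FOXA3, APOB, AFP and SOX7 at 1.29 ± 0.41, -1.06 ± 0.52, -0.64 ± 0.42 and -1.02 ± 0.70 had the smallest p. Of 31 fibroblast genes 2 rose, adjusted over the list alone, MMP2 and PDGFRB at 1.57 ± 0.43 and 1.87 ± 0.52, while COL6A2 stood at 1.64 ± 0.52. Of 9 endothelial and blood genes 2 rose, adjusted over the list alone, TIE1 at 1.30 ± 0.43 and CDH5 from 0.244 to 1.3 CPM, beside ERG at -1.18 ± 0.63, and VWF at 0.452 CPM in the controls and 1.14 CPM after knockdown. No HOX gene had enough counts for edgeR's test, and DESeq2 fitted 11 and called 0 higher and 0 lower (0 and 0 at an unadjusted p under 0.05). DESeq2 gave 18626 of 33109 genes no adjusted p. How many of the 11 HOX genes were among these, and so could not be called, was not counted. Median deviations in knockdown replicates 1 to 4 were 0.90, 0.46, 0.33 and -0.09 for trophoblast and amnion and 0.33, 0.06, 0.28 and 0.06 for mesoderm. The remaining medians were -0.04, -0.31, -0.20 and 0.08 for endoderm, 0.83, 0.04, 0.23 and -0.04 for fibroblast and 0.13, -0.35, -0.36 and 0.18 for endothelial and blood genes. The medians of endoderm (-0.20) and of endothelial and blood genes (-0.04) turned positive under scaling by library size only. Once the GC trend was removed, higher and lower members, adjusted over the list alone, numbered 0 and 0 in each of these 5 lists. Leaving out knockdown replicate 4 gave, over all genes, higher and lower counts of 4 and 0 for trophoblast and amnion, 3 and 2 for mesoderm and 2 and 2 for endoderm. Further counts were 10 and 2 for fibroblast and 3 and 2 for endothelial and blood genes. Median log2 fold changes as fitted, with GC removal and without knockdown replicate 4 were 0.14, -0.23 and 0.32 for trophoblast and amnion, 0.27, -0.25 and 0.34 for mesoderm and -0.20, -0.22 and -0.38 for endoderm. In that order they were 0.24, 0.05 and 0.34 for fibroblast and -0.04, 0.08 and -0.24 for endothelial and blood genes. The median had the other sign in 7 of 22 alternatives for trophoblast and amnion, 5 of 22 for mesoderm, 4 of 22 for endoderm and 7 of 22 for endothelial and blood genes, and never for the others. GC removal moved the log2 fold change of members named as passing by over 1.5 times, to 0.18 for KRT7, 0.23 for KRT18, 0.06 for KRT8, -1.09 for HAPLN1, 0.85 for MMP2, 1.11 for PDGFRB and 0.37 for TIE1. Trophoblast and amnion genes had a median GC content of 60.2%. Camera called none of these 5 lists on the edgeR fit, and gave calls in 1 of 22 alternatives for fibroblast and none for the others. Camera, which sets a list against all other genes, gave a downward direction for the pluripotency, m6A writer and eraser, and mesoderm lists (adjusted p = 0.92, 0.76 and 0.92 on the edgeR fit), whose medians and means lay above 0. These medians did not keep their sign in every alternative, and with GC removal camera's direction for the m6A list turned upward (adjusted p = 0.59 on the edgeR fit). It gave the downward direction for endothelial and blood genes too (adjusted p = 0.92), whose mean of 0.26 lay above 0.

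Of 39 unfolded protein and integrated stress response genes 13 rose and 0 fell, adjusted over the list alone, among them CHAC1, a glutathione-degrading enzyme, SDF2L1 and AARS (alanyl-tRNA synthetase) at log2 fold changes of 2.39 ± 0.48, 2.06 ± 0.46 and 1.01 ± 0.26, and DDIT4 from 0.31 to 2.07 CPM. Of 40 p53 targets 12 rose and 1 fell, adjusted over the list alone, and BTG1, SLC12A4, PLK3 and XPC at 1.29 ± 0.32, 1.49 ± 0.41, 2.00 ± 0.55 and 1.18 ± 0.34 led them. Camera did not call the p53 list (adjusted p = 0.059 on the edgeR fit), and with the GC trend removed it did (adjusted p = 0.008, and adjusted p = 0.87 with an estimated correlation). Of 31 cholesterol and fatty acid synthesis genes 9 rose, adjusted over the list alone, among them TM7SF2, FASN (fatty acid synthase), MVD and LSS at 1.62 ± 0.38, 1.77 ± 0.42, 1.26 ± 0.33 and 1.27 ± 0.34. Of 25 glycolysis genes 4 rose, adjusted over the list alone, the glucose transporter SLC2A1, PFKL and ALDOA at 1.39 ± 0.38, 1.39 ± 0.38 and 1.30 ± 0.40 and SLC16A3 from 0.182 to 3.47 CPM. Of 30 immediate early genes 1 rose, adjusted over the list alone, ETV4 at 1.68 ± 0.41, beside DUSP1 and SPRY4 at 1.65 ± 0.53 and 1.2 ± 0.40, and NR4A1 at 0.337 CPM in the controls and 1.78 CPM after knockdown. None of 18 heat shock genes passed in edgeR (2 higher and 4 lower at an unadjusted p under 0.05, and 1 higher and 2 lower of 18 by DESeq2). The smallest p were those of CHORDC1, FKBP4, DNAJB1 and HSPE1 at -1.36 ± 0.42, 0.92 ± 0.33, 0.82 ± 0.30 and -1.01 ± 0.37. None of 39 interferon response genes passed in edgeR (8 higher and 4 lower at an unadjusted p under 0.05, and 4 higher and 4 lower of 48 by DESeq2). IFITM1, TAP1, BST2 and IFI35 at -1.09 ± 0.33, 1.48 ± 0.47, 0.99 ± 0.33 and 1.26 ± 0.43 had the smallest p. In knockdown replicates 1 to 4 the median member deviated by 0.70, 0.52, 0.22 and 0.03 for the unfolded protein list, 1.04, 0.76, 0.61 and 0.07 for p53 and 0.20, 0.31, 0.22 and 0.21 for cholesterol synthesis. For the others it deviated by 0.47, -0.01, 0.49 and -0.07 for glycolysis, 0.72, 1.04, 0.24 and -0.23 for immediate early, -0.29, -0.30, -0.26 and -0.03 for heat shock and 0.45, -0.09, 0.37 and 0.09 for interferon response genes. With GC removal the counts of higher and lower members, adjusted over the list alone, were 5 and 0 for the unfolded protein list, 5 and 1 for p53, 2 and 3 for cholesterol synthesis and 2 and 1 for glycolysis. Further counts were 0 and 2 for immediate early, 1 and 4 for heat shock and 0 and 3 for interferon response genes. Without knockdown replicate 4 the counts higher and lower over all genes were 18 and 7 for the unfolded protein list, 21 and 6 for p53, 13 and 10 for cholesterol synthesis and 11 and 10 for glycolysis. The rest gave 13 and 1 for immediate early, 3 and 6 for heat shock and 10 and 7 for interferon response genes. As fitted, with GC removal and without knockdown replicate 4, median log2 fold changes were 0.53, 0.23 and 0.72 for the unfolded protein list, 0.66, 0.39 and 0.84 for p53 and 0.32, 0.04 and 0.09 for cholesterol synthesis. The same 3 medians were 0.27, -0.12 and 0.38 for glycolysis and 0.69, 0.45 and 0.96 for immediate early. The same 3 medians were -0.18, -0.35 and -0.27 for heat shock and 0.31, -0.02 and 0.31 for interferon response genes. Alternatives gave a median of the other sign in 3 of 22 for cholesterol synthesis, 3 of 22 for glycolysis, 1 of 22 for heat shock and 3 of 22 for interferon response genes, and never for the others. Named members that had passed moved by over 1.5 times with GC removal, to 1.22 for CHAC1, 0.72 for SDF2L1, 0.67 for AARS, 0.47 for SLC12A4, 0.97 for PLK3, 0.54 for TM7SF2, 0.46 for FASN, 0.10 for MVD, 0.44 for LSS, 0.87 for SLC2A1, 0.18 for PFKL, 0.23 for ALDOA and 0.62 for ETV4. Camera called none of these 7 lists on the edgeR fit, and it called them in 3 of 22 alternatives for the unfolded protein list, 6 of 22 for p53, 5 of 22 for immediate early and 3 of 22 for heat shock and none for the others. The heat shock median of -0.18 turned positive under scaling by library size only.

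**Figure D3:**
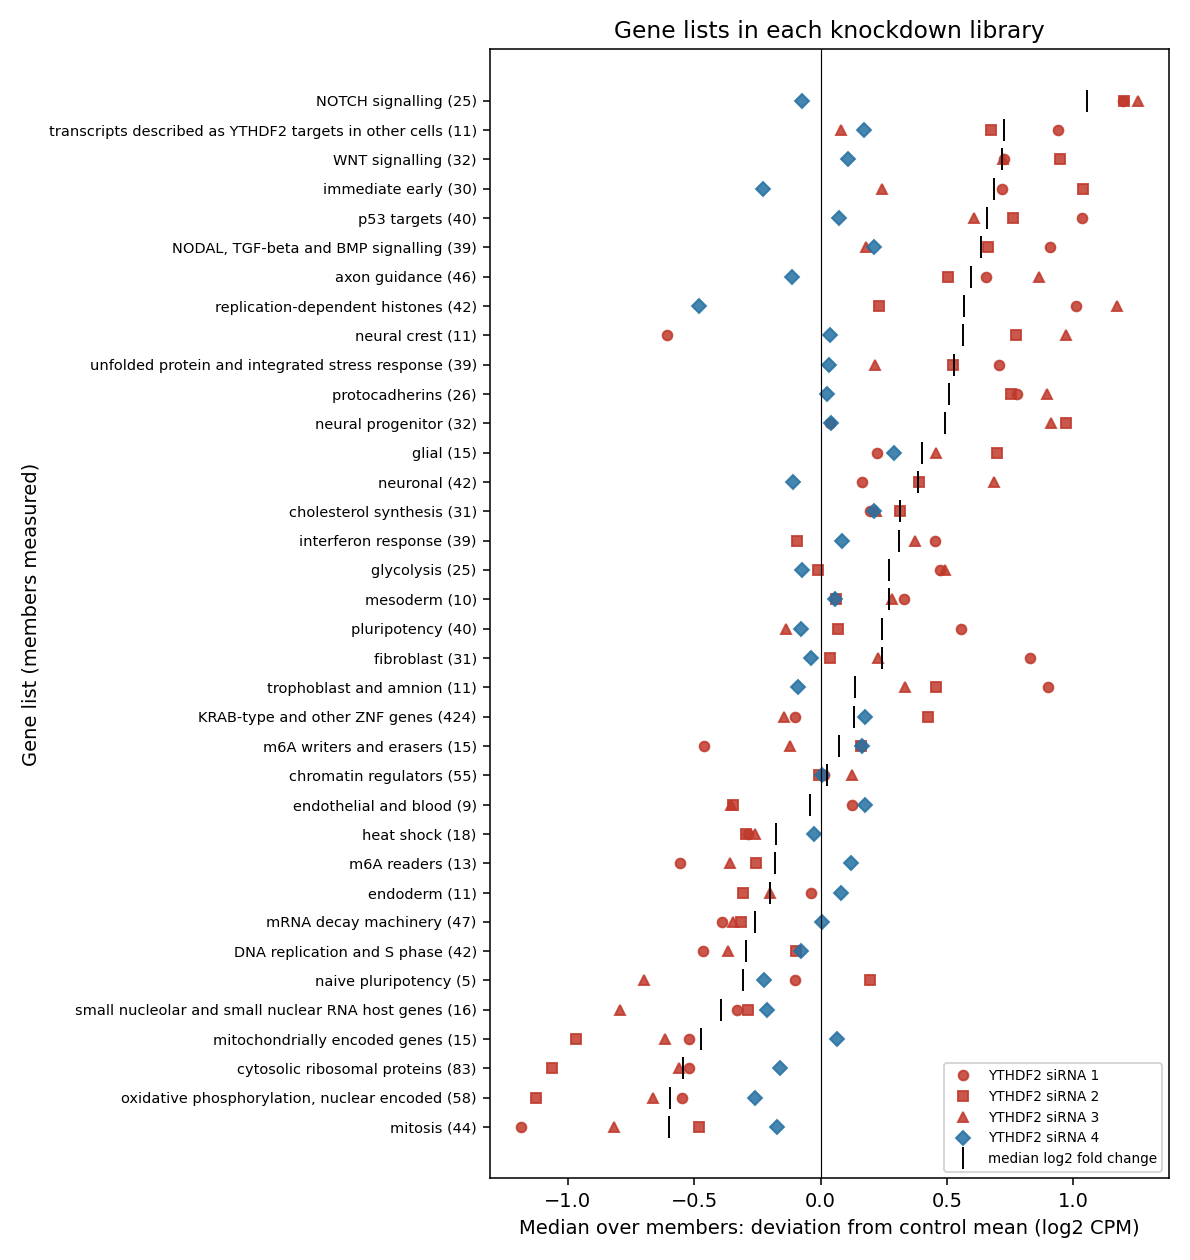
Median deviation from the control mean (x axis, log2 CPM) of the measured members of each of 36 gene lists (y axis, number measured in parentheses) in knockdown replicates 1 to 3 (red) and 4 (blue), with the list's median log2 fold change as a black bar. NOTCH genes lie between 1.2 and 1.26 in replicates 1 to 3 and at -0.08 in replicate 4, while mitosis, oxidative phosphorylation and ribosomal protein genes lie below 0 in all 4, under TMM scaling.

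With the GC trend removed, a setting chosen after the data were seen, the rule for named genes gave 12 protein-coding genes in each direction at edgeR adjusted p under 0.05 and with no overlap between the groups. Those that rose were CISD3, TSPYL4, NDNL2, TWF1, AGO2, BTG1, HIPK3, PELO, AKT1, RGS10, PAQR8 and GEMIN8, with log2 fold changes of 2.13, 2.07, 2.00, 1.98, 1.88, 1.88, 1.79, 1.78, 1.77, 1.76, 1.74 and 1.72. AGO2 is the slicer of the RNA interference pathway, BTG1 an antiproliferative factor that binds the deadenylase complex, and PELO a ribosome rescue factor. Those that fell besides YTHDF2 were SCML2, HIST1H1D, DIRC2, TSNAX, AFMID, GUCD1, CGN, TLK1, LRTOMT, TEX14 and TMEM33, with -2.05, -1.86, -1.82, -1.77, -1.75, -1.75, -1.68, -1.67, -1.65, -1.65 and -1.59. YTHDF2 itself stood at -1.66 ± 0.19 in that fit. Fitted without the removal, AKT1, HIPK3 and GUCD1 differed from these values by over 1.5 times, at 2.70, 1.17 and -1.01. With the trend removed, the 4 knockdown libraries of each of these genes lay on the same side of the 3 controls, which was part of the rule. Replicate 4 deviated least from the control mean in each of them except YTHDF2, HIST1H1D and DIRC2. For the genes that rose it deviated by 0.31 (GEMIN8) to 1.45 (TWF1), and replicates 1 to 3 by 1.29 (PELO) to 2.83 (CISD3). For those that fell besides YTHDF2 it deviated by -1.70 (HIST1H1D) to -0.52 (LRTOMT), and replicates 1 to 3 by -3.08 (TSNAX) to -1.46 (HIST1H1D). With the trend removed and knockdown replicate 4 left out, edgeR called 2426 higher and 2830 lower genes, 566 of the 568 among them. CISD3 had no GC value, so its counts were not corrected. Of the 568 genes called, 90.3% were protein-coding against 84.4% of those tested (Fisher's exact test, p = 3.6e-05). Genes are not independent replicates, so this p does not measure the spread between libraries.

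Of the genes named, 61 overlap another annotated gene, among them POU5F1, NGFR, FEN1, KRT8 and KRT18, HSPE1, IFITM1, LRTOMT and TSNAX, and whether the counting used strand is not given in the sources used here, so reads of such neighbours may be mixed. Ribosomal protein, histone, zinc finger and protocadherin genes also share sequence with copies or pseudogenes, and their values are uncertain to that extent.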

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

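Within the 4 knockdown libraries a value is listed here where 1 library's gap to its nearest neighbour, relative to the range of all 4, passed Dixon's 95% limit, which chance passes in about 1 of 20 groups. The tests of GC bias of libraries, alone and as the whole cause, of the depth of YTHDF2 depletion, the count of splits for genes without GC removal, and the removal of the GC trend itself were chosen only after the result was seen.

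Of 12 library measures 2 passed that limit, of 36 list medians 4 and of 170 named genes 14, and replicate 4 was the library concerned in 2, 3 and 12 of these. Replicate 4 had 12231034 counts, against 22287525 to 24140756 in the others, and with the GC trend removed it stood at -32.9 on the first principal component, against 51.2 to 56.0. Its median heat shock gene deviated by -0.028 (others -0.297 to -0.261), its median NOTCH gene by -0.075 (1.195 to 1.256) and its median protocadherin by 0.027 (0.752 to 0.894). Replicate 3 had a chromatin regulator median of 0.124 (-0.007 to 0.012). In CPM, replicate 4 was lower than the others for GEMIN8 (10.5 against 32.3 to 35.2), SNAI1 (0.762 against 1.78 to 1.87), PDGFRB (1.43 against 4.10 to 4.49), BMP7 (3.81 against 8.97 to 9.66) and SLC2A1 (30.1 against 90.6 to 103). It was higher for AFMID (49.0 against 23.6 to 26.5), CGN (9.24 against 7.12 to 7.34), TLK1 (268.2 against 37.6 to 73.5), HSPE1 (818 against 261.9 to 338.4), ZNF532 (62.9 against 42.9 to 43.9), MT-CO1 (23330 against 8283 to 10470) and MT-ND5 (1811 against 810.5 to 895.5). GFAP was lower in replicate 2 (0.951 against 1.72 to 1.80 CPM), and FOXA3 higher in replicate 1 (19.04 against 6.67 to 8.30 CPM).

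Knockdown replicates 1 to 3 lay apart from the controls on the main axis of variation, and replicate 4 lay with the controls. Stronger depletion of YTHDF2 in the 3 libraries is argued against by 14.4 CPM in replicate 4, inside their range of 11.9 to 17.4 and far from the 46.9 to 52.1 CPM of the controls, which also argues against a control library under a knockdown label. Thinning every library to the smallest total left the lowest correlation of replicate 4 with a control 0.0373 above the highest of the other 3, so library totals do not account for it. A GC-dependent bias of the libraries may contribute, since the correlation with transcript GC was at least 0.571 in the 3 libraries and -0.0228 in replicate 4. A gap of 0.0141 stayed after GC removal (0.0337 before), which argues against this bias as the whole cause only if the removal was complete. The removal used a single GC value per gene, and its completeness was not tested. What also stays open is a further difference in how the libraries were made, since no batch is given in the labels, or a difference between the cultures in their response, which was not tested.

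The 4 knockdown libraries also shared changes beyond YTHDF2. With the GC trend removed and YTHDF2 left out, the deviations of each from 1 control correlated with those of the other 3 from another control at 0.495, 0.504, 0.529 and, in replicate 4, 0.113, against -0.0246 to 0.0256 for the controls. Splits of the libraries cannot test the real count of 0 genes, since 35 of 35 reach 0 by construction. The highest other count was 8781, from the split of knockdown replicates 1 to 3 against the rest, which points to a structure of the samples. After GC removal, 2 of 35 splits called as many as the real 568, the other being that same split with 5377, so chance is not excluded.

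Gene lists shifted with the knockdown, and their shifts followed GC content. Across the 36 lists, which share members and are not independent, Spearman's rho of the median log2 fold change with the median GC content was 0.527 (permutation p = 0.0012) and Pearson's r 0.532, so part of the shifts may come from GC content. As the whole cause it was predicted to leave no list called once the GC trend was removed. The test cannot decide this, since camera's preset correlation also gave 6 or more lists in 25 of 35 splits before removal, the real one included. The completeness of the removal was not tested either. With the GC trend removed 6 lists were called at that correlation. Of these, 3 (mitosis, oxidative phosphorylation and ribosomal proteins) were also called before removal and 3 were not. With an estimated correlation none was called, before removal (adjusted p = 0.82 to 0.97) or after it (0.87 to 0.93). Chance is not excluded for the number of lists, since 25 of 35 splits called as many as the real 6, with 13 as the highest other, and a response to the loss of YTHDF2 stays open as a hypothesis.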

How the results depend on the processing

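The settings with the GC trend removed were chosen only after the result was seen. The log2 fold change of YTHDF2 kept its direction in all 22 alternatives, from -2.02 to -1.32, and its adjusted p lay between 2.4e-11 and 0.20, with 11 not under 0.05. The count of 0 changed genes stayed at 0 with DESeq2 or upper-quartile factors in edgeR, a filter of 1 CPM, limma-voom, protein-coding genes only, a threshold of 0.01, and a 1.5-fold minimum. It was 3652 with library size only, 3284 with no filter, 3106 with DESeq2, 9983 with limma-voom and library weights, 1 with the gene-length trend removed (lower), 3756 at a threshold of 0.10, 568 with the GC trend removed and 5256 when knockdown replicate 4 was left out as well. Leaving out each library gave 0 to 8300 genes, the highest without knockdown replicate 4. Of the 568 genes, DESeq2 called 426 and the fit without replicate 4 490, 487 of these in the same direction. The 6 called lists became 3 with library size only, 12 with no filter, 3 with a filter of 1 CPM, 15 with DESeq2 and 11 with the GC trend removed and replicate 4 left out, and 3 to 9 without each library in turn, the lowest without knockdown replicate 2. Mitosis, oxidative phosphorylation and ribosomal proteins were called in all 22 alternatives, WNT was lost in 11, NOTCH in 7 and mitochondrial genes in 8. The correlation of fold change with exon junctions per kb went from -0.0522 to -0.2012 with the GC trend removed, and lay between -0.0700 and -0.0134 without each library. The library weights were lowest for knockdown replicate 4 (0.123, against 0.393 to 2.75 in the other libraries), so the weighted fit rests little on it. Apart from this weight and the replicate block, whose construction is given below, the cause of these shifts was not tested. Over the 170 named genes and their alternatives, 2367 values were on the same side of the threshold, 1301 passed it only in the alternative, 26 had the other sign and passed in neither, and 2 had the other sign and passed in the alternative. The last both concern KRT19, at 0.63 in the comparison and -0.48 with the GC trend removed and the replicate block, or -0.49 with replicate 4 left out.

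With the replicate number as a block 8533 genes were called (8 lists), 8297 with the gene-length trend also removed (12 lists) and 5212 with the GC trend also removed (11 lists). Samples with the same number did not deviate together (correlations of 0.0201, -0.0109 and 0.0029). Each knockdown library was set against the mean of its group, from which replicate 4 stands apart, so these values cannot decide on pairing. The labels do not say whether the numbers pair the samples. Knockdown replicate 4 has no control of its number, takes a coefficient of its own in the block and drops out of the comparison, as when it is left out. At the spread of these 7 libraries the simulated data recovered 16% of 2-fold and 94% of 4-fold changes. Changes of 2-fold may therefore be missed, but genes varied independently there and these rates need not hold in the real libraries. In the real comparison larger differences did not pass either. AKT1, 6.5-fold higher, and YTHDF2, 3.4-fold lower, each had an edgeR adjusted p = 0.0572.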

Other observations

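The removal of the GC trend was chosen only after the result was seen, whereas the tests of transcript structure were chosen before theirs.

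Camera called 6 lists on the edgeR fit once the GC trend was removed. Zinc finger genes, many of them transcription factors with KRAB repressor domains, lay higher around a median log2 fold change of 0.26 (adjusted p = 0.012, and adjusted p = 0.87 with an estimated correlation), and in knockdown replicates 1 to 4 the median member deviated by 0.26, 0.44, 0.14 and 0.12. Host genes of small nucleolar RNAs lay lower around -0.39 (adjusted p = 0.028, and adjusted p = 0.87 with an estimated correlation), with -0.52, -0.28, -0.58 and -0.25 in the 4 libraries. The others were p53 targets, higher, and mitosis, oxidative phosphorylation and ribosomal protein genes, lower, and each of these 4 calls was also lost with an estimated correlation (adjusted p = 0.87). Tested for change in either direction without removal, fry called the glial and mesoderm lists (adjusted p = 0.0352 for both), and with the GC trend removed it called 26 of the 36 lists, those 2 among them. That test does not set a list against other genes. With the GC trend removed, 4443 of all 16007 tested genes had an unadjusted p under 0.05 in edgeR. The number of lists called does not by itself set them apart.

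Because m6A lies mostly in long exons and near stop codons, transcripts with few exon junctions per kb and long 3' UTRs were used as a stand-in for methylated transcripts, over 13502 protein-coding genes, which are not independent replicates, on the hypothesis that they are higher once YTHDF2 is lost. Before GC removal, rho with junctions per kb was 0.0028, -0.1108, 0.0027 and -0.1177 in knockdown replicates 1 to 4 (controls -0.0556 to 0.0549) and rho with 3' UTR length -0.1989, -0.0827, -0.1665 and 0.059 (-0.0324 to 0.04), so 2 and 1 of 4 libraries lay beyond the controls in the predicted direction. After it, rho with junctions per kb was at most -0.1124 (lowest -0.2294), against -0.0583 to 0.0463 in the controls, and rho with 3' UTR length at least 0.0477 (highest 0.1444), against -0.0276 to 0.0247, in the predicted direction in 4 of 4 libraries. Replicate 4 lay beyond the controls before and after for both features, whereas the junction trend of replicates 1 and 3 and the 3' UTR trend of replicates 1 to 3 rest on the removal. The removal took the rho of the fold change from -0.0522, matched in size by 24 of 35 splits, to -0.2012 for junctions and from -0.1453 to 0.1234 for 3' UTRs. A GC-dependent bias was predicted to let the junction rho move toward 0 on removal, and it grew instead. Since the junction trend did not stand in replicates 1 and 3 before removal, this growth cannot decide, and a GC-dependent bias or its correction is not excluded. Splits matched the rho in size in 3 of 35 cases for junctions and 4 of 35 for 3' UTRs after removal, so chance is not excluded, and fold changes also fell with mean expression (rho -0.3587), so the trends may have other sources and the hypothesis stays open.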
